A study of Homo sapiens with 3 samples.

How the data were processed

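Total RNA from KYSE150 cells was extracted with Trizol, turned into biotin-labelled cRNA and hybridised to PrimeView human arrays, per the labels' protocols and the series design. The labels give 3 groups of 1 array each, overexpressing LOXL2 Δe13, overexpressing wild-type LOXL2 or carrying an empty vector. The deposited values are log2 probe set signals made by the authors with RMA, per the submitters' processing notes, which corrects background, normalizes between arrays and summarises probes into probe sets. The RMA version is not given in the sources used here, and the log2 scale was read from the range of the values, 2.07 to 14.56. RMA forces the arrays onto similar distributions, so a shift of most genes in one direction would not show. Scanner files were not used here.

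Each array held 49395 probe sets, of which 102 were controls. Gene names came from the platform annotation in GEO, with symbols updated through Entrez IDs in an NCBI RefSeq table of assembly GRCh38.p14, used for names alone. A single symbol was given to 44994 probe sets (91.3% of the non-control ones), several symbols to 1832, and 2467 were not listed and so stayed unnamed here. The Entrez IDs of 27 probe sets were not in the RefSeq table. Probe sets with a single symbol covered 18132 genes, 11734 of them with more than 1 probe set. No probe positions or genome coordinates were used.

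A gene was represented by its probe set with the highest mean over the 3 arrays. The floor was the median of all non-control values, 5.94, and a gene entered a comparison if the higher of its 2 values reached it. Differences were taken between log2 values in 3 comparisons. With 1 array per group no test, standard error or p-value was possible, and genes were counted by a fixed size of 2-fold. Spread between probe sets of the same gene was the only repeat measurement; its standard deviation was 0.13 for Δe13 minus the empty vector, 0.16 for wild type minus the empty vector and 0.13 for Δe13 minus wild type. It covers probe set error and not the spread between cultures. Signals near or below the floor hold much background, which compresses folds.

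Named genes were the 12 highest and 12 lowest per comparison among genes whose probe sets above the floor all differed in the same direction, the LOX family, and up to 4 members of each gene list with the largest difference in the direction of its median, with members at least 2-fold the other way. Genes outside this rule are said to be chosen after their values were seen. Of 43 gene lists, 29 symbols were updated and 7 left out as ambiguous or not found. Members with a mean above the floor entered, and a list with fewer than 5 was not compared. The median difference of a list was placed among those of 10000 random lists of the same size, matched on mean expression in 10 bins, and a list stood apart below percentile 0.5 or above 99.5. This describes these arrays; random lists ignore that genes of a pathway vary together, so a list can stand apart through ordinary variation between cultures.

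The groups, lists, rules and alternatives were fixed before the data were examined, apart from the tests and gene family named as later choices in the closing part. Alternatives were the median over a gene's probe sets, no floor, a floor at the 75th percentile (7.86), centring on the median, quantile normalization, loess on mean signal with a span of 0.3, thresholds of 1.5-fold and 3-fold, random lists without matching, and percentiles of 2.5 and 97.5. Chance values for the shared control came from 1000 simulations of unchanged arrays, with the spread per gene taken from Δe13 minus wild type by level of expression.

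The rules were tested on simulated data built on the 10703 genes of Δe13 minus the empty vector with a mean above the floor. The 2-fold rule found 0 of 50 genes changed by 0.585 (log2), 21 of 50 changed by 1.0, and 50 of 50 changed by 1.5 or by 2.0, and it called 0 of 10503 unchanged genes. The simulated noise was normal, with a robust standard deviation per array of at most 0.13, taken from Δe13 minus wild type. With such noise a 2-fold call of an unchanged gene was all but impossible, so this result does not measure false calls in the real arrays. Of 100 lists of 20 genes shifted by 0.05, 0.1 and 0.2, 7, 38 and 93 stood apart upward, and of unshifted lists 0. The 100 lists were placed in the same simulated pair of arrays and shifted together, so the random lists also drew on shifted genes. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.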

Results

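KYSE150 is an established line of human esophageal squamous cell carcinoma. LOXL2, lysyl oxidase like 2, is a secreted copper-dependent amine oxidase known for cross-linking collagen and elastin. The cells had been made to overexpress wild-type LOXL2 or a splice form of it called LOXL2 Δe13, and control cells carried an empty vector. Expression was measured on PrimeView arrays, with 3 arrays in all and 1 per group. Each array gave a log2 signal for 49395 probe sets, and the array medians were 5.95 for LOXL2 Δe13, 5.93 for wild-type LOXL2 and 5.95 for the empty vector. The comparisons ask which genes differ when the splice form is overexpressed, and how it compares with the wild-type form and with the control. Nothing was replicated, so every difference below is between individual arrays, carries no error between cultures and was not tested. The number of arrays limits the precision. Values are log2 differences unless called folds, and the words higher and lower describe these arrays alone.

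The overexpressed gene separated the arrays by probe set. On LOXL2 probe set 11718833_a_at the signal was 10.77 in the Δe13 array and 10.22 in the wild-type array, against 5.06 in the empty vector array. These were log2 differences of 5.71 and 5.16. Probe set 11718834_at was also higher in both LOXL2 arrays, by 2.56 for Δe13 and by 2.69 for the wild type. The empty vector signals on these probe sets lay below the expression floor of 5.94. Probe set 11751288_a_at was high in the wild-type array alone, at 14.05 against 7.46 in the empty vector array, a difference of 6.59 or 96.1-fold. The Δe13 array gave 7.41 on it, which was -0.05 relative to the control. Probe set 11718832_a_at was high in none of the LOXL2 arrays relative to the control, at 8.73 for Δe13, 8.32 for the wild type and 8.81 for the empty vector. Which part of the transcript each probe set reads is not given in the sources used here, so a probe set outside the expressed sequence would check nothing.

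**Figure D1:**
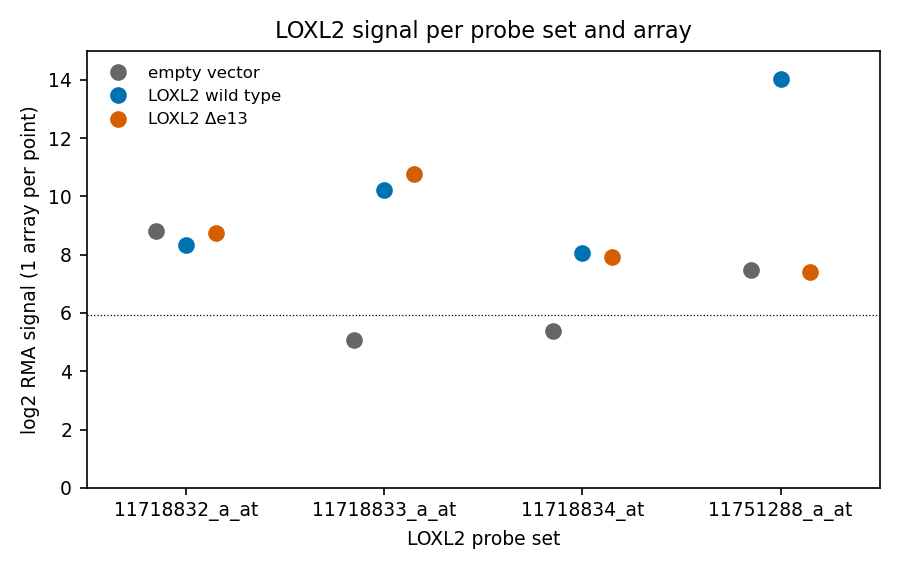
Log2 RMA signal (y axis) of the 4 LOXL2 probe sets (x axis) in the empty vector, wild-type LOXL2 and LOXL2 Δe13 arrays, with 1 point per array and a dotted line at the expression floor of 5.94. Probe sets 11718833_a_at and 11718834_at were higher in both LOXL2 arrays than in the control, while 11751288_a_at reached 14.05 in the wild-type array and 7.41 in the Δe13 array.

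Among the relatives of LOXL2, LOXL4 was lower in both LOXL2 arrays, by a log2 difference of -0.74 for Δe13 and -0.63 for the wild type. LOXL1 differed by 0.28 and 0.20, and LOX by 0.00 and -0.06. LOXL3 stayed below the expression floor.

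LOXL2 Δe13 was compared with the empty vector to find the genes that differ when the splice form is overexpressed. Genes of the unfolded protein response, together with the chaperone gene HSPA6, were among those with the largest positive differences. HSPA6, a stress-inducible chaperone of the HSP70 family, was higher by 1.83, from a control signal of 5.51 that lay below the floor. DDIT3, the transcription factor CHOP of the endoplasmic reticulum stress response, was 2.59-fold higher, with 2 of 2 probe sets in the same direction. HSPA5, the main HSP70 chaperone of the endoplasmic reticulum, was 2.03-fold higher, and its 6 probe sets gave log2 differences between 1.03 and 2.08. HERPUD1, a protein of endoplasmic reticulum-associated degradation, was 2.05-fold higher on 3 of 3 probe sets.

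In all, 10878 genes passed the floor in this comparison, of which 5 were at least 2-fold higher and 1 at least 2-fold lower in the Δe13 array. The remaining gene at least 2-fold higher was ARRDC4, an arrestin-domain protein, at 2.16-fold. Just short of that size were GEM, a small GTP-binding protein (0.99), the transcription factor KLF10 (0.89), ODC1, the rate-limiting enzyme of polyamine synthesis (0.87), and the siderophore-binding lipocalin LCN2 (0.84, from a control signal of 5.82 below the floor). PICALM and SYTL2 each differed by 0.81, as did IFRD1. The gene at least 2-fold lower was TNKS2, a tankyrase, at -1.14 on 1 probe set, whose Δe13 signal of 5.59 lay below the floor; with the floor at the 75th percentile it was no longer counted. PHLDA1 differed by -0.95 on 4 of 4 probe sets, and TMT1A by -0.97. The basal keratin KRT15 and the water and glycerol channel AQP3 each differed by -0.83, and the epithelial ETS factor EHF by -0.78. CLIC3 (-0.91), RAB26 (-0.81), ALDH3B2 (-0.80), the inflammasome protease CASP1 (-0.79) and GNE, an enzyme of sialic acid synthesis (-0.76), completed the lowest named genes with LOXL4. The Δe13 signals of ALDH3B2, CASP1 and GNE lay below the floor.

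Gene lists fixed in advance were compared with random lists of matched expression. Of 38 lists compared, 3 stood apart above and 7 below the random lists, where 0.38 were expected outside by construction. The unfolded protein response list had a median difference of 0.44, with 21 of 23 members higher. Of these members 6 were at least 1.5-fold higher, among them DNAJB11 at 0.75. The disulfide isomerase PDIA3, chosen after its value was seen, was lower at -0.75. Replication-dependent histone genes had a median of 0.50, with 7 of 8 members higher, such as H2AC6 at 0.70 and H2BC11 at 0.63. The list of MYC and ribosome biogenesis targets had a median of 0.14, with 22 of 23 members higher, led by ODC1 and by the nucleolar proteins NOP58 and RRP12 at 0.40 each.

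Lipid synthesis genes were lower in the Δe13 array. All 16 cholesterol synthesis genes above the floor were lower, with a median of -0.24 and with MSMO1 at -0.47, SQLE at -0.45 and FDPS at -0.42. Fatty acid synthesis genes had a median of -0.25 with 8 of 9 lower, including the acetyl-CoA synthetase ACSS2 (-0.55), the elongase ELOVL6 (-0.46) and the desaturase SCD (-0.39). Mitosis and G2/M genes had a median of -0.12 with 30 of 34 lower, such as CDC25B at -0.41 and CCNA2 at -0.36. NRF2 targets had a median of -0.18 with 11 of 15 lower, including TKT at -0.50 and HMOX1 at -0.45. The matrix metalloproteinase list had a median of -0.20 with 7 of 9 lower, including MMP28 at -0.64 and MMP14 at -0.40. Basal squamous markers had a median of -0.17 with 6 of 7 lower, KRT15 and KRT14 (-0.46) foremost. The ATF4 amino acid response list had a median of -0.11 with 13 of 20 lower, such as PHGDH at -0.41, while its member DDIT3 was higher at 1.37. The metalloproteinase, basal squamous, ATF4, NRF2 and fatty acid lists no longer stood apart under at least 1 other setting. GC-rich background probe sets on the arrays were also lower here, by a median of -0.06.

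**Figure D2:**
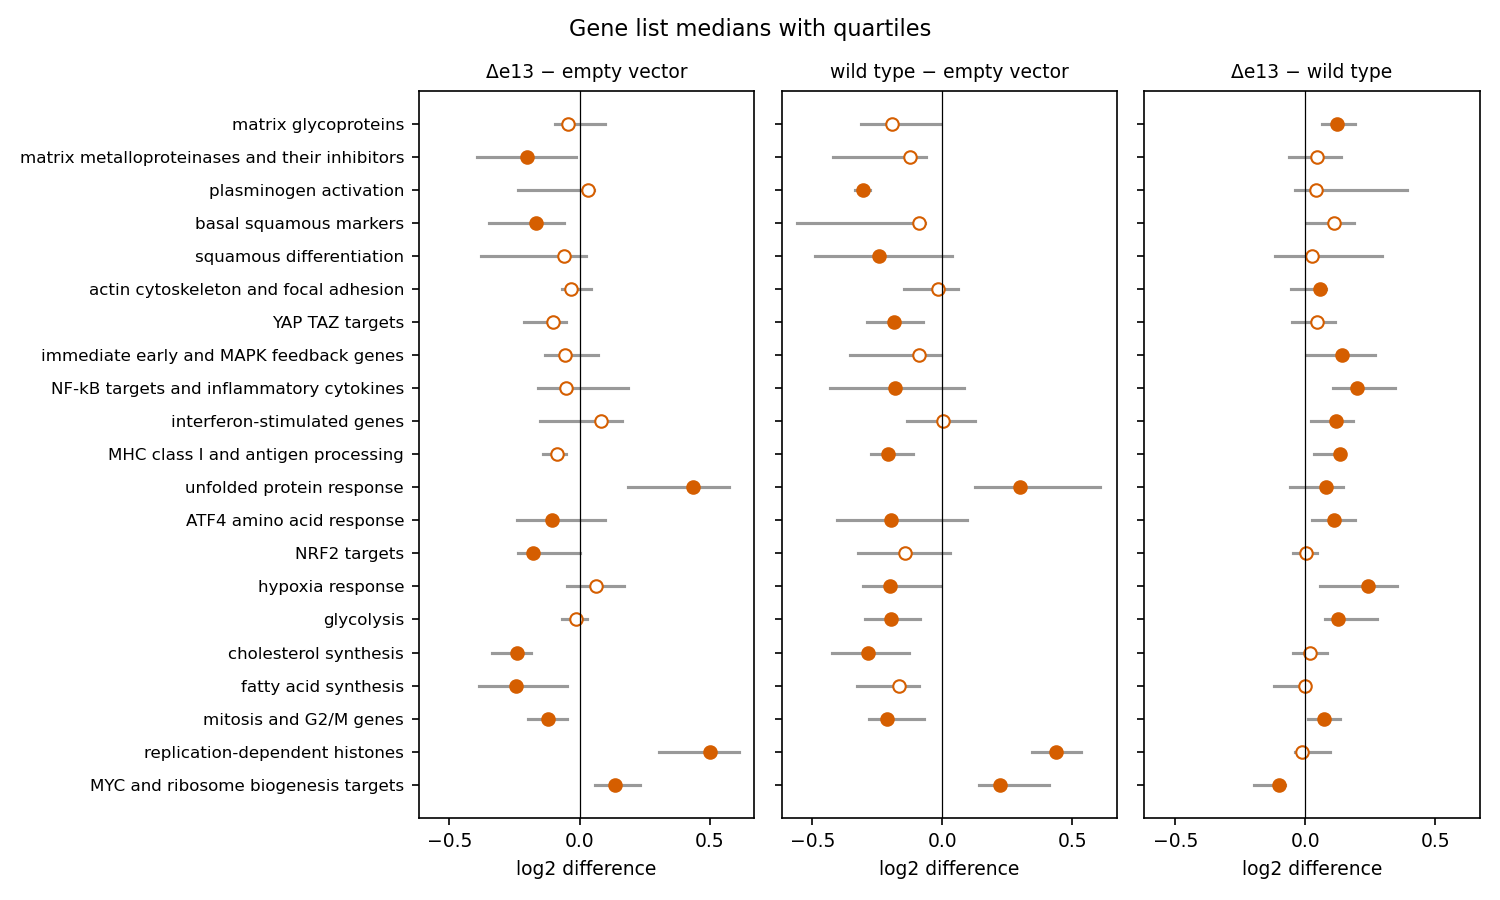
Median log2 difference (x axis) of each gene list that stood apart from random lists in at least 1 comparison (y axis), with 1 panel per comparison; filled points stood apart, open points did not, and grey lines span the quartiles of the members. The unfolded protein response list had medians of 0.44, 0.30 and 0.08 from left to right, and the hypoxia response list 0.06, -0.20 and 0.24.

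Wild-type LOXL2 was compared with the empty vector as the reference for the splice form. Apart from LOXL2 itself, ARRDC4 had the largest positive difference among the genes named, at 2.85-fold. EHF was lower by a log2 difference of -1.66, with a wild-type signal of 5.49 below the floor. The stress genes seen with Δe13 were higher here too, with DDIT3 at 2.04-fold and HSPA6 at a difference of 1.09 from its control signal below the floor. GEM (2.60-fold), KLF10 (2.23-fold) and ODC1 (2.22-fold) were higher, as were the dehydrogenase DHRS2 (2.36-fold) and LIG4, the DNA ligase of non-homologous end joining (2.30-fold, from a control signal of 5.95 just above the floor). The lipid droplet protein HILPDA was 2.11-fold lower on 2 of 2 probe sets, and the glycolytic aldolase ALDOC 2.11-fold lower on 5 of 5.

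The comparison held 10881 genes above the floor, with 21 at least 2-fold higher and 11 at least 2-fold lower. The standard deviation of the differences over genes was 0.26, against 0.18 for Δe13 minus the empty vector. ABCA13 (1.46), GRIP1 (1.35), the nuclear receptor NR4A3 (1.27) and the zinc finger genes ZSCAN12 (1.21) and ZNF425 (1.17) were higher from dim control signals of 4.80, 4.75, 5.09, 5.03 and 5.57, below the floor. PHLDA1 was 2.36-fold lower on 4 of 4 probe sets and RAB26 2.06-fold lower. ZNF436-AS1 (-1.09 on its highest probe set), RDM1 (-1.05), KRT15 (2.0-fold lower) and CLIC3 (-0.97) followed. GNE (-1.16), CEL (-1.0) and ZBED2 (-0.99) were lower with wild-type signals of 5.09, 5.39 and 5.88, below the floor. Where genes at least 2-fold apart had several probe sets above the floor, all probe sets went the same way in 9 of 13 genes.

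Of the 38 lists, 3 stood apart above and 10 below in the wild-type array. The 3 above were those seen with Δe13. The unfolded protein response list had a median of 0.30 with 19 of 23 members higher, including HSPA5 at 0.93, HERPUD1 at 0.88 and DNAJB11 at 0.79. Histone genes had a median of 0.44 with 7 of 8 higher, and H2BC5 led them at 0.81. MYC and ribosome biogenesis targets had a median of 0.22 with 22 of 23 higher, including NOP58 at 0.63 and RRP12 at 0.62.

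Lists below the random range in the wild-type array covered oxygen, metabolism, inflammation and cell division. Hypoxia response genes had a median of -0.20 with 13 of 18 lower, including ANKRD37 at -0.86 and the peptide hormone gene ADM at -0.78. Glycolysis genes had a median of -0.20 with 13 of 16 lower, ALDOC foremost and then ENO2 at -0.33 and PGK1 at -0.32. Cholesterol synthesis genes had a median of -0.29 with 15 of 16 lower, including SQLE at -0.73 and MSMO1 at -0.64. NF-kB targets and inflammatory cytokines had a median of -0.18 with 10 of 15 lower, including IL1B at -0.92 and IL1A at -0.76. MHC class I and antigen processing genes had a median of -0.21 with 11 of 12 lower, such as TAPBP at -0.35. Mitosis and G2/M genes had a median of -0.21 with 30 of 34 lower, such as CCNB2 at -0.44 and AURKB at -0.43. The ATF4 list had a median of -0.20 with 13 of 20 lower, including DDIT4 at -0.66 and GDF15 at -0.61, while DDIT3 was higher at 1.03. YAP and TAZ targets had a median of -0.19 with 10 of 11 lower, such as CCN2 at -0.35. Plasminogen activation genes had a median of -0.31 with 4 of 5 lower, PLAU at -0.50 foremost, and squamous differentiation genes a median of -0.25 with 5 of 8 lower, such as CSTA at -0.75. The plasminogen, squamous differentiation, YAP and TAZ, NF-kB and MHC class I lists no longer stood apart under at least 1 other setting. GC-rich background probe sets were lower as well in this array, by a median of -0.22.

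**Figure D3:**
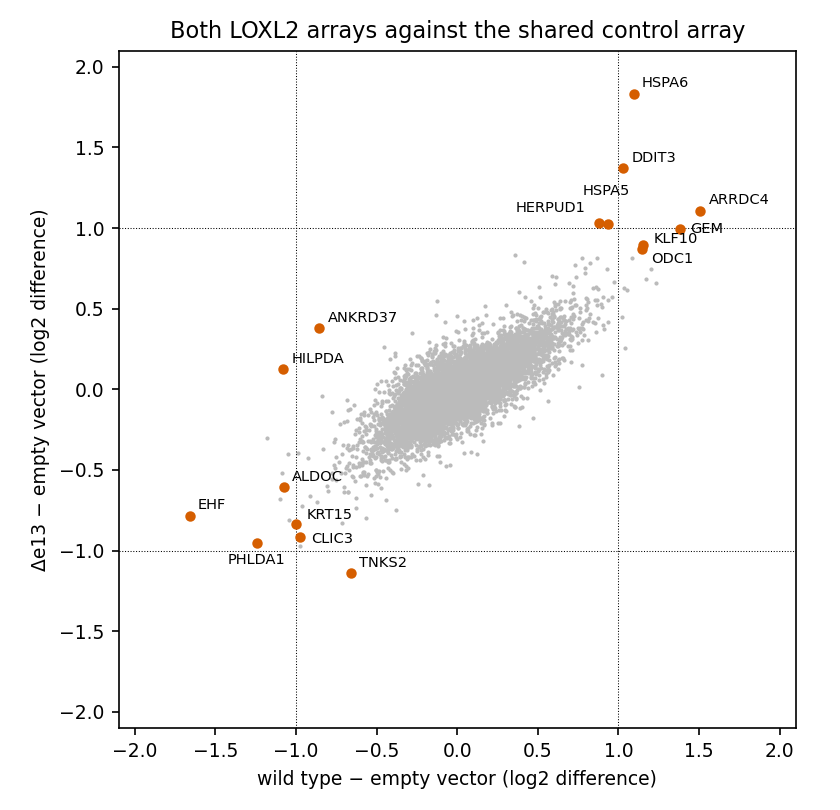
Log2 difference from the empty vector array for wild-type LOXL2 (x axis) and LOXL2 Δe13 (y axis), with 1 grey point per gene whose mean signal passed the floor, LOXL2 left out, named genes in orange and dotted lines at 2-fold. HSPA6, DDIT3 and ARRDC4 lie at least 2-fold higher on both axes, and HILPDA and ANKRD37 lie at -1.08 and -0.86 on the x axis and at 0.12 and 0.38 on the y axis.

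LOXL2 Δe13 was compared directly with wild-type LOXL2 to set the splice form apart from the full form. Of the hypoxia response list, 16 of 18 genes were higher in the Δe13 array. Its member ANKRD37, an ankyrin repeat gene, was 2.36-fold higher. ADM was 1.56-fold higher on 3 of 3 probe sets, and BNIP3, a mitochondrial protein of mitophagy, 1.54-fold higher. HILPDA, which is not on that list, was 2.30-fold higher on 2 of 2 probe sets. The gene lower by at least 2-fold was LOXL2 itself, through probe set 11751288_a_at at -6.64, while 11718833_a_at was higher by 0.54.

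Of 10847 genes above the floor, 2 were at least 2-fold higher and 1 at least 2-fold lower, and the differences over genes had a standard deviation of 0.17. EHF (0.88), the acute phase gene SAA1 (0.80), HSPA6 (0.74), GPRC5A (0.72), the kinase FYN (0.67), AGRP (0.66), RDM1 (0.64) and the clock gene PER1 (0.62) followed among the named genes. KRCC1 (-0.81), RABGAP1L (-0.80), the splicing factor SRSF8 (-0.78), TP53I3 (-0.77) and ZMYM6 (-0.74) were the lowest named genes after LOXL2. Zinc finger genes ZFP37 (-0.70), ZNF181 (-0.68) and ZNF398 (-0.63) were also among the 12 lowest named genes, with FAM135A (-0.65), SANBR (-0.64), SECISBP2L (-0.63) and BCDIN3D (-0.61). The lower of the 2 signals lay below the floor for EHF, AGRP, RABGAP1L, SRSF8, TP53I3, ZFP37, ZNF181, SANBR and BCDIN3D.

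Here 11 of the 38 lists stood apart above and 1 below. The hypoxia response list had the highest median of these, 0.24, with 3 members at least 1.5-fold higher. Against the control its median in the Δe13 array, 0.06, lay inside the random range of -0.10 to 0.10. NF-kB targets and inflammatory cytokines had a median of 0.20 with 13 of 15 higher, including IL1B at 0.50 and IL1A at 0.45. Glycolysis genes had a median of 0.12 with 15 of 16 higher, including ALDOC at 0.47 and ENO2 at 0.41. Immediate early and MAPK feedback genes had a median of 0.14 with 16 of 22 higher, such as ETV5 at 0.38 and DUSP6 at 0.32. Interferon-stimulated genes had a median of 0.12 with 19 of 25 higher, such as IFIT1 at 0.36, and MHC class I genes a median of 0.13 with 10 of 12 higher. The ATF4 list had a median of 0.11 with 16 of 20 higher, such as DDIT4 at 0.54, and the unfolded protein response list a median of 0.08 with 13 of 23 higher. Matrix glycoproteins (0.12, with 10 of 11 higher), mitosis and G2/M genes (0.07, with 27 of 34 higher) and actin cytoskeleton genes (0.06, with 18 of 29 higher) made up the rest. The list below was that of MYC and ribosome biogenesis targets, with a median of -0.10 and 21 of 23 lower, led by ODC1 and UTP20 at -0.28 each. The matrix glycoprotein, actin and MYC lists no longer stood apart under at least 1 other setting. This comparison shares its wild-type array with wild type minus the empty vector. The hypoxia, NF-kB, glycolysis, MHC class I, mitosis and ATF4 lists stood apart below there. The Δe13 medians of the last 5 of these against the control were -0.053, -0.012, -0.085, -0.123 and -0.106. Being higher than in the wild-type array thus did not place them above the control. GC-rich background probe sets were higher in the Δe13 array than in the wild-type array by a median of 0.16, in the same direction as the 11 lists.

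**Figure D4:**
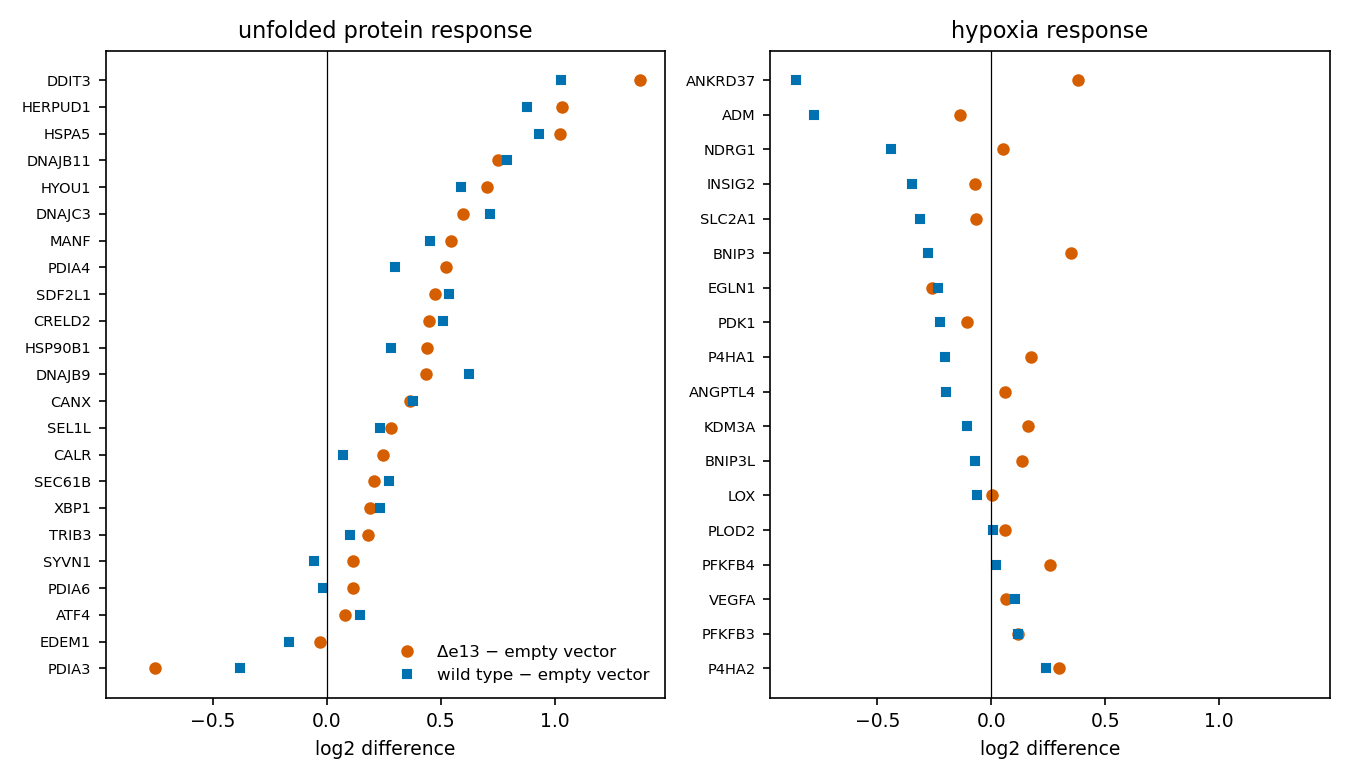
Log2 difference from the empty vector array (x axis) of the members of the unfolded protein response list (left) and the hypoxia response list (right), named on the y axis, with circles for LOXL2 Δe13 and squares for wild-type LOXL2, 1 value per array pair. In the left panel 21 of 23 circles and 19 of 23 squares lie above zero; in the right panel 13 of 18 circles lie above zero and 13 of 18 squares below it.

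Both LOXL2 arrays were set against the shared empty vector array. ARRDC4, DDIT3 and HSPA6 were at least 2-fold higher in both, and no gene was at least 2-fold lower in both. At 1.5-fold, 33 genes were higher in both and 24 lower in both, and 0 went opposite ways. Independent lists of the same lengths would share 0.70 and 0.31 genes, and simulated unchanged arrays sharing 1 control shared 0.14 genes on average. Across the 10703 genes with a mean above the floor, the differences correlated with r = 0.77, against a mean of 0.50 in the simulation, and 77.5% had the same sign, against 66.6%. The covariance was 0.0341, against a simulated mean of 0.0098. The simulated spread came from Δe13 minus wild type, which does not hold the deviation of the empty vector array itself. Genes are not independent replicates, and the control, with 1 array, could not be split. Part or all of the excess may therefore come from the shared control.

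Other lists did not stand apart in any comparison. Mesenchymal markers had medians of 0.09, -0.01 and 0.04 for Δe13 minus the empty vector, wild type minus the empty vector and Δe13 minus wild type, and epithelial junction markers -0.01, 0.03 and -0.06 in the same order. Collagens, the substrates known for the LOX family, had medians of 0.02, 0.01 and 0.05, and integrins -0.10, -0.18 and 0.04. Heat shock chaperones had medians of 0.049, 0.125 and -0.066, with 7, 8 and 5 of 13 members higher. The difference of HSPA6 was therefore not shared by that list as a whole. Its member HSPA1B was higher than in the control by 0.77 for Δe13 and 0.73 for the wild type. It was the 1 member at least 1.5-fold higher in each of these comparisons. Leukocyte markers, with 5 of 14 genes above the floor, had medians of 0.03, -0.14 and 0.17. Few markers of other cell types passed the floor: 3 of 14 for fibroblasts, 2 of 11 for endothelium and 4 of 10 for melanocytes and neuroendocrine cells, too few to compare.

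The 3' minus 5' signal of the ACTB control probe sets was 1.38 for Δe13, 1.46 for the wild type and 1.26 for the empty vector, and that of GAPDH was -0.03, 0.00 and -0.01.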

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

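The tests of an array exchange, of the unread sequence, of the background gradient, of a trend with signal level and of normalization were chosen after the results were seen; the gene lists, their random ranges and the scalings themselves were fixed before.

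LOXL2 itself differed between the LOXL2 arrays by -6.638 (Δe13 minus wild type) on probe set 11751288_a_at, which was -0.052 from the control in the Δe13 array and 6.586 in the wild-type array; this difference in direction was not tested. An exchange of the empty vector array with a LOXL2 array is argued against by 2 LOXL2 probe sets that exceeded the control by more than 1 (log2) in both LOXL2 arrays. A candidate explanation is that this probe set reads sequence the Δe13 transcript does not carry, but the value of -0.052 prompted it and so does not test it. Because the probe positions are not given, this stays open, as do other differences between the 2 expression constructs and an exchange of the 2 LOXL2 arrays with each other, which no probe set of known position excludes.

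Genes of the unfolded protein response were higher in both LOXL2 arrays than in the control. A gradient across the arrays of the kind seen in GC-rich background probe sets would give the Δe13 array 0.287 of the wild-type difference, but the median remainder after removing it was 0.257 (95% bootstrap interval over genes, which vary together, 0.153 to 0.394). The Δe13 median of 0.435 lay above the random range. The list was flagged for being higher in both LOXL2 arrays, and the remainder is built from the same values. Neither therefore adds separate support against the gradient. The Δe13 median was opposite in sign to the background shift of -0.062. The GC content of the list's probe sets was not used, so the sign alone decides nothing. A trend with signal level spanned -0.075 to 0.045 in the wild-type array. Its size argues against it as the whole cause of the list median of 0.30 there. Loess removed the trend and left 0.312 (interval 0.159 to 0.52). With so small a trend, and with random lists already matched on mean expression, that outcome was all but fixed in advance and adds no separate support. Other effects of normalization stay open, because the signals were already RMA-normalized and centring or quantile normalization moved the median of all genes by at most 0.015. The state of the empty vector culture cannot be told apart from an effect of LOXL2, since 1 such culture was measured, and an endoplasmic reticulum load from any secreted protein remains an untested biological explanation.

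Genes of the hypoxia response had medians of opposite sign in the LOXL2 arrays against the control, 0.063 for Δe13 and -0.202 for the wild type, but the Δe13 value lay inside the random range of -0.099 to 0.098 and the difference was not tested. The list median was 0.242 for Δe13 minus wild type, with its member ANKRD37 at 1.235 (0.379 and -0.857); HILPDA, which is not on the list, was at 1.202 (0.123 and -1.079). The trend with signal level, of -0.075 to 0.045, is argued against by its size as the whole cause in the wild-type array. Loess left -0.199 there (interval -0.309 to -0.021), which was all but fixed in advance for the same reasons as above. Other effects of normalization stay open, as centring or quantile normalization moved the median of all genes by at most 0.02, and so does a gradient like that of the GC-rich background probe sets: their wild-type shift was -0.216, and the remainder of 0.102 (interval 0.033 to 0.209) concerns the Δe13 array alone. The state of the wild-type culture, such as its density or oxygen supply at harvest, cannot be told apart from an effect of the wild-type form, since 1 such culture was measured; a difference between the LOXL2 forms stays open as an untested biological explanation.

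Probe sets without a single gene symbol lay outside the gene comparisons and still held signal. Of 1994 such probe sets passing the floor, 1 was at least 2-fold higher in the Δe13 array than in the control, by 3.828. Of 2013, 5 were at least 2-fold higher in the wild-type array, the highest by 2.889.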

How the results depend on the processing

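The alternatives fixed in advance were run on the 24 highest and lowest genes named per comparison, on LOXL2 and on the lists that stood apart; the other genes named were not recomputed. Among these, 0 genes apart from LOXL2 and 0 list medians changed direction. For the named genes this was mostly fixed in advance. They were chosen for probe sets above the floor that all went the same way, and changing the floor leaves a gene's value as it was. Of 388 recomputed gene values 380 moved little and 8 moved further, all with the median over a gene's probe sets. The 72 values without a floor and the 28 with the higher floor equal the original ones by construction. The same holds for the median over probe sets where a gene had 1 probe set above the floor. The 380 therefore overstates how stable the values are. Of 243 recomputed results of lists that stood apart, 219 still stood apart and 24 did not. Centring shifts every gene of a comparison alike, so its 35 results stood apart by construction. Random lists without matching left the medians as they were and changed the percentiles alone, with 30 still apart and 5 not. The 219 therefore overstates how stable the lists are. The unfolded protein response, histone, hypoxia, glycolysis, cholesterol and mitosis lists stood apart under all of these settings wherever they did so in the comparisons above. The median over probe sets moved LOXL2 to 1.25 for Δe13 and 3.93 for the wild type against the control, and reversed Δe13 minus wild type to 0.136, because the LOXL2 probe sets disagree. Counts of genes at least 2-fold apart followed the threshold by construction. At 1.5-fold they were 39 higher and 33 lower for Δe13 minus the empty vector, 220 and 100 for wild type minus the empty vector, and 20 and 13 for Δe13 minus wild type. At 3-fold they were 1 and 0, then 1 and 1, then 0 higher, with LOXL2 the gene that stayed lower. With the floor at the 75th percentile, which admits fewer genes, Δe13 minus the empty vector kept 0 lower, and wild type minus the empty vector 8 higher and 7 lower. With the median over probe sets, wild type minus the empty vector gave 6 lower, 5 of them among the original 11, and the cause was not tested. Under the same setting Δe13 minus wild type gave 0 lower, because LOXL2, the gene counted before, moved to 0.136. Without a floor, which admits 18132 genes instead of 10847, Δe13 minus wild type gave 2 lower, 1 of them the original gene. The correlation between the differences from the control was 0.789 with the median over probe sets, 0.667 without a floor and 0.808 with the higher floor; the cause was not tested. Centring, quantile normalization and loess left every one of these counts within 1.5 times its value. No paired analysis was possible because each group had 1 array, and for the same reason no array could be left out. Over all comparisons together, 14 of 19 entries at least 2-fold apart with several probe sets (73.7%) had all probe sets in the same direction. The share was 54.1% without a floor and 84.6% with the higher floor. An entry is a gene in a comparison, and some genes, such as LOXL2 and DDIT3, enter in more than 1. The other shares lay inside the 95% interval of the first, 51.2 to 88.2%. That interval treats entries as independent and the sets overlap, so an effect of the floor was not tested.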

Other observations

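The gene family described here was chosen after the data were seen. Genes with symbols starting ZNF, most of them zinc finger proteins, were higher in the wild-type array. Of 268 such genes with a mean above the floor, 185 were higher than in the control, with a median difference of 0.15. At 1.5-fold, 22 were higher and 3 lower. In the Δe13 array 158 were higher, with a median of 0.05, and Δe13 minus wild type gave a median of -0.10 with 79 higher. Under centring, quantile normalization and loess the medians kept their signs, at 0.12 to 0.15 for wild type minus the empty vector and -0.09 to -0.08 for Δe13 minus wild type. The signals were already RMA-normalized, and centring or quantile normalization moved the median of all genes by at most 0.02. Kept signs under these scalings therefore decide little.

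Control probe sets differed between the arrays as well. Background probe sets with low GC content had medians of 0.00, 0.00 and 0.01 for Δe13 minus the empty vector, wild type minus the empty vector and Δe13 minus wild type, whereas those of high GC content had -0.06, -0.22 and 0.16. Those of high GC content kept these signs under the same scalings, with -0.22 to -0.19 for wild type minus the empty vector, which decides little for the same reason. Hybridisation spikes had medians of -0.18, -0.09 and -0.08, and the poly-A spikes 0.03, -0.11 and 0.12, in the same order.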
